A study of Sus scrofa with 2 samples.

How the data were processed

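RNA from 2 cultures of pig embryonic cells was sequenced, with 1 library from embryonic germ cells (pEGC) and 1 from fetal fibroblasts (pFF). Per the labels' protocols, poly(A) RNA was selected in 2 rounds, treated with DNase, fragmented by hydrolysis and copied into double-stranded cDNA from random hexamers, and no step that keeps the strand is described. The deposited values are positions and not counts: each file lists 1 aligned read per line with its chromosome, start, end and strand, without a header, and the authors' files keep repeated lines. The aligner, the genome build, the treatment of reads with several matches and any filter are not given in the sources used here. Each file held 14324517 lines, each spanning 34 bases, on chromosomes 1 to 18 and X. The equal number of lines means that the files may not hold all reads of the deeper library, and no source used here says how it arose. The files list no read on the Y chromosome, the mitochondrial genome or unplaced sequence, so none of these was analysed here.

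The reference gene table at hand is on the assembly Sscrofa11.1. On 6 of the 19 chromosomes the highest read position lay beyond the last gene of that table. The files were therefore taken to use another assembly, and coordinates were not carried over. Chromosomes can run on past their last gene, so this comparison alone is not proof. Genes could therefore not be named. The gene part of the plan fixed before the data were examined, with 20 anchor genes and 29 gene lists (pluripotency, germ line, fibroblast matrix and other cell types and pathways), could not be evaluated, and the rule for regions covered by reads, fixed in the same plan, was used instead. All coordinates are those of the deposited files, written with the first base counted as 1 under the BED convention, which no label states, so they may be off by 1 base.

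The reads of both libraries were pooled and sorted, and reads whose starts lay within 200 bases of the next were joined into a region if at least 20 pooled reads fell in it. The join distance and this minimum were set after the files had been seen. A region is thus a stretch covered by reads and not a gene, and its limits depend on both libraries. How regions relate to exons was not examined, since no annotation was used. Of the pEGC reads, 12910575 fell in regions, and of the pFF reads 13672805. Levels were computed here as RPM, the reads of a region scaled to a common total of reads in regions. The ratio of the libraries has an exact 95% interval (Clopper-Pearson, from the pEGC reads among the pooled reads of the region). Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only, and with 1 library per group they say nothing about the spread between cultures. With 20 reads in each library the interval of an equal ratio runs from 0.511 to 1.96, with 50 reads from 0.662 to 1.51 and with 1000 reads from 0.915 to 1.09. A count of 0 was replaced by a floor of 3 reads, which is 0.232 RPM in pEGC and 0.219 RPM in pFF. Other counts were kept, so a count of 1 gives a larger ratio than a count of 0.

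A region was counted as higher in 1 library if its RPM was at least 4-fold that of the other, the higher library had at least 50 reads and the interval lay beyond 2-fold. This is a rule of size that compares 2 libraries. It is not a test of the conditions, and no p-value is given. On simulated reads for the 75535 regions, with 200 regions changed, the rule found 50 of 50 regions made 8-fold different and 50 of 50 made 16-fold different. It found 0 of 50 made 2-fold different, 0 of 50 made 3-fold different and 0 of 75335 made equal, and 96.2% of the intervals held the simulated ratio. The changed regions were drawn only from those with at least 200 pooled reads, so finding them says nothing about regions near the minimum of 50 reads. Many of the regions made equal had too few reads to pass the rule at all. The simulated reads were independent draws, without repeated positions and without a general shift between the libraries. The simulation therefore checks the rule against counting error only and gives no rate of false calls for the real libraries. A region was counted as detected with at least 10 reads and at least 1 RPM. Listed by a rule fixed in advance are the 10 regions with the largest ratio in each direction among those with at least 200 reads in the higher library, and the 5 regions with the most reads in each library. Neighbouring regions of 1 direction were also joined into loci where they lay within 20 kb of each other with no region of the other direction between them. Loci were defined after the regions had been seen, and those named are the ones with the most reads or the most regions. The correlation of the libraries was taken across regions on log2(RPM + 1).

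Alternatives fixed in advance were other scalings (a trimmed mean of M-values with 30% of the ratios and 5% of the levels trimmed, a median of ratios, and a total without the 50 regions with most reads), each read position counted once, thinning pFF to the pEGC total of reads in regions (block included, so depth outside the block stayed unequal), other minimums of reads, an 8-fold rule, other detection limits and other pseudocounts. Other join distances, fixed windows of 10 kb and leaving out 1 dominant block of chromosome 6 were added after the data had been seen. Parts of a named locus are its called regions joined over 10 kb instead of 20 kb, also added then. Counting reads by overlap instead of midpoint was not run, since the regions are built from the reads and both rules assign the same reads. The code used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.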

Results

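The data comprised poly(A) RNA sequencing of 2 primary cultures from pig embryos taken between days 17 and 24 of gestation. Embryonic germ cells (pEGC) are colonies grown from primordial germ cells, the embryonic precursors of sperm and eggs, and fetal fibroblasts (pFF) are connective tissue cells. The labels describe the animals as a cross of Danish Landrace and Yorkshire pigs, whereas the series title speaks of mini pigs. The germ cell colonies were grown on inactivated STO cells, a mouse fibroblast line used as a feeder layer, with LIF at 10 ng/ml, SCF at 10 ng/ml and bFGF at 3 ng/ml. The labels do not describe the culture of the fibroblasts. Each culture had 1 library of 14324517 aligned reads, and there were no replicates. All values below therefore compare 2 libraries, and their intervals cover counting error only. Reads from feeder cells that align to the pig genome cannot be separated from pig reads in these files.

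The first question was how the reads of each library were spread over the genome. A block of chromosome 6 between positions 247440 and 259306 took 30.6% of the pFF reads (exact 95% interval 30.57 to 30.62) and 11.5% of the pEGC reads (11.45 to 11.48). The block consisted of 3 regions. The region from 257239 to 259306 had 195959 RPM in pFF and 63483 RPM in pEGC and was 3.09-fold higher in pFF (3.08 to 3.09). The region from 247440 to 253625 had 124392 RPM in pFF and 63653 RPM in pEGC, a ratio of 1.95 (1.95 to 1.96). The small region between them, from 254798 to 255861, had 157 RPM in pFF and 73.3 RPM in pEGC, a ratio of 2.14 (1.98 to 2.31). The profile of reads along the block was similar in both libraries (Spearman rho 0.871 over 63 bins of 100 bases, which are not independent). Outside the block, the 100 regions with most reads took 21.4% of the pFF reads and 13.9% of the pEGC reads.

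**Figure D1:**
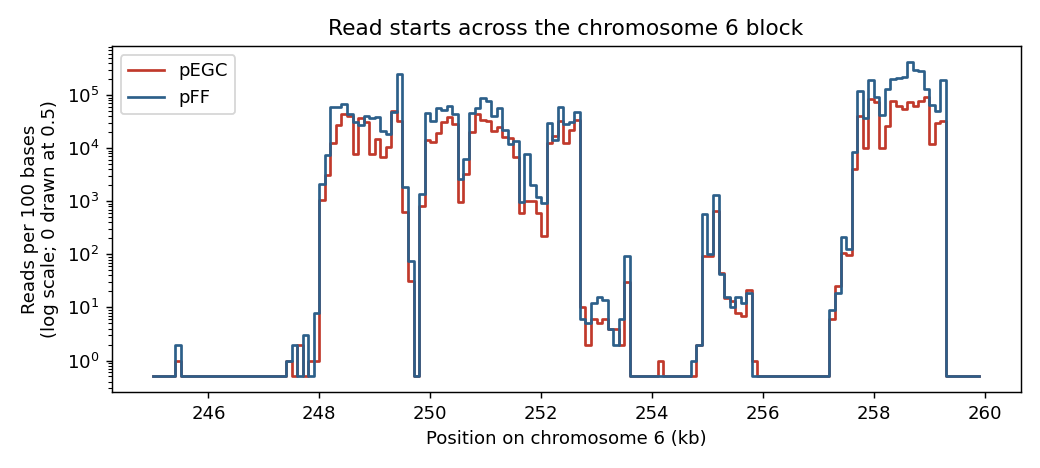
Read starts per 100 bases (log scale, with 0 drawn at 0.5) across the block of chromosome 6, with the position in kb on the horizontal axis, 1 library per line. The stretches at 248 to 252.7 kb and 257.6 to 259.3 kb carry nearly all reads of the block, and pFF lies above pEGC in most of their bins.

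The second question was how much of the genome was transcribed in each culture. With at least 10 reads and 1 RPM, 67264 of 75535 regions were detected in pEGC and 48364 in pFF. Both libraries shared 42073 of these, 25191 were detected in pEGC and not in pFF, and 6291 in pFF and not in pEGC. The size of this gap depended on the scaling. Outside the chromosome 6 block, pEGC had 12682182 reads and pFF 9942281, so pFF had less depth there. With the block left out, 68375 regions were detected in pEGC and 56026 in pFF. Of these, 19360 and 7011 were detected in that library alone. With the trimmed mean of M-values, 61172 regions were detected in pEGC and 53994 in pFF, of which 17785 and 10607 were detected in that library alone. Reads outside regions, in places with fewer than 20 pooled reads, made up 9.87% of the pEGC library (9.86 to 9.89) and 4.55% of the pFF library (4.54 to 4.56). Distinct combinations of position and strand made up 44.0% of the pEGC reads and 26.8% of the pFF reads. With 9942281 reads outside the block drawn from each library, these shares were 53.4% and 38.5%. Among 1589 regions with nearly equal read numbers in the 2 libraries, between 100 and 400 reads each, 57.5% of the pEGC reads and 50.1% of the pFF reads had distinct positions. Across all regions, log2(RPM + 1) of the libraries correlated with Pearson r = 0.698 and Spearman rho = 0.506, where regions are not independent replicates.

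The distance between reads on opposite strands also differed between the libraries. Distinct starts on strand F had a start on strand R, among distances of 75 bases or more, most often 145 bases downstream in pEGC (8.31% of F positions) and 175 bases downstream in pFF (9.30%), against 4.54% and 4.53% at 300 bases. With the 34 bases of a read added, these distances give a most frequent fragment of about 179 bases in pEGC and 209 bases in pFF. The shares of reads on strand F were 49.8% and 49.5%.

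**Figure D2:**
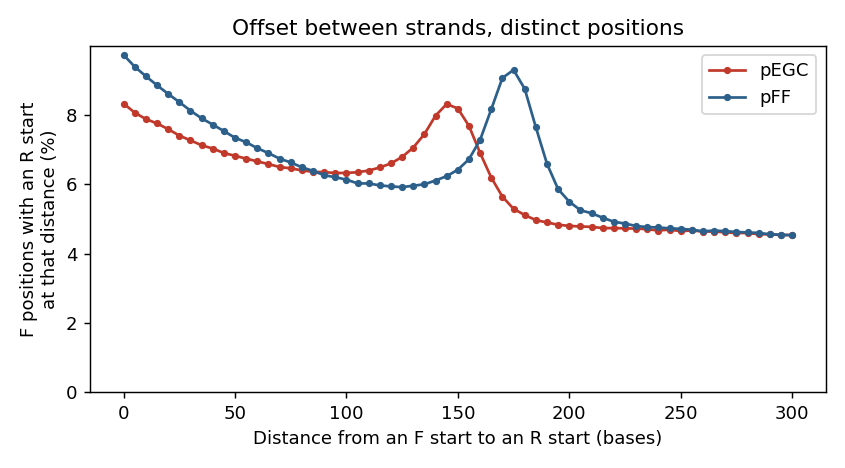
Share of distinct F starts (%) that have an R start at a given distance (bases), 1 line per library, without chromosome 6. Both curves fall from 0 bases and peak again at 145 bases in pEGC and at 175 bases in pFF.

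The main comparison asked which transcribed regions differed between germ cells and fibroblasts. By the 4-fold rule 6606 regions were higher in pEGC and 2303 were higher in pFF, out of 32206 that had enough reads to qualify, so 74.1% of the differing regions were higher in pEGC. This split depended on the scaling: the median log2 ratio of pEGC over pFF in these 32206 regions was 0.75, and with a trimmed mean of M-values, which moved it to -0.02, the numbers were 4194 and 3438, or 55.0% higher in pEGC. The median of ratios gave 4144 and 3501, or 54.2%. Without the chromosome 6 block in the totals they were 5241 and 2725, or 65.8%. With the trimmed mean of M-values 4194 of the 6606 regions higher in pEGC remained in their group. All 2303 higher in pFF remained by construction, since that scaling raises every fold in favour of pFF. Folds given below are not centred. The trimmed mean of M-values would divide each fold in favour of pEGC by 1.71 and multiply each in favour of pFF by the same factor. Regions higher in pEGC held 20.1% of the pEGC reads in regions, and those higher in pFF held 15.4% of the pFF reads in regions. The other library had 3 reads or fewer in 1359 of the regions higher in pEGC and in 827 of those higher in pFF.

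**Figure D3:**
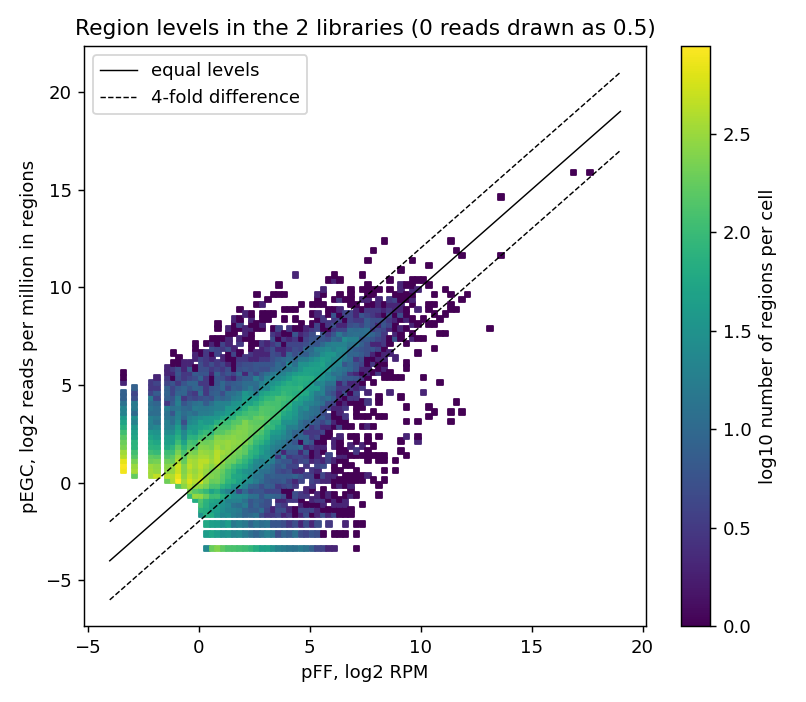
Level of each of the 75535 regions in pFF (horizontal) and pEGC (vertical) as log2 RPM, coloured by the number of regions per cell of the grid, with lines for equal levels and for a 4-fold difference. The cloud lies above the line of equal levels (median log2 ratio 0.83 over all regions), and a tail of regions with high pFF levels lies below the lower 4-fold line.

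Regions higher in pFF formed 1063 loci, of which 727 were single regions and 30 held 10 or more. The fold of a locus is that of its summed reads, and its regions were picked because they differ. The locus with the most regions lay on chromosome 1 from 128655708 to 128774690, where 51 separate short regions were higher in pFF over 119 kb. Together they had 2074 RPM in pFF and 11.2 RPM in pEGC, a 185-fold difference (157 to 219), with single regions from 41.5-fold to 643-fold. A stretch of chromosome 15 from 88041536 to 88149340 held 44 regions in 2 unlike parts. The 17 regions up to 88081132 had 5142 RPM in pFF and 26.6 RPM in pEGC (194-fold, 174 to 216), and the 27 regions from 88096017 on had 2659 RPM and 267 RPM (9.97-fold, 9.63 to 10.3). A locus on chromosome 1 from 95859275 to 95990978 held 45 regions and was 19.2-fold higher in pFF (18.0 to 20.5). By number of reads, the leading pFF loci were a single region of 17.9 kb on chromosome 1 from 138127337 to 138145259, with 13635 RPM in pFF and 2961 RPM in pEGC (4.60-fold, 4.55 to 4.66), and 8 regions on chromosome 15 from 110934963 to 111013129, with 12635 RPM and 2537 RPM (4.98-fold, 4.92 to 5.04). The locus on chromosome 9 from 69420490 to 69456812 had 10579 RPM in pFF and 300.1 RPM in pEGC (35.3-fold, 34.1 to 36.4). Abundant loci with few pEGC reads lay on chromosome 14 from 105764301 to 105786249, with 8006 RPM in pFF against 31.7 RPM in pEGC (253-fold, 229 to 279), and on chromosome 12 from 24667493 to 24690234, with 4549 RPM against 21.6 RPM (211-fold, 187 to 238).

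Regions higher in pEGC formed 2682 loci, of which 1514 were single regions and 101 held 10 or more. The most abundant lay on chromosome 14 from 11444155 to 11469939, with 10301 RPM in pEGC and 616 RPM in pFF, 16.7-fold higher in pEGC (16.4 to 17.1). Loci on chromosome 16 from 15499459 to 15560963, with 3622 RPM in pEGC and 242 RPM in pFF (15.0-fold, 14.5 to 15.5), and on chromosome 9 from 65833407 to 65937077, with 2886 RPM and 166 RPM (17.4-fold, 16.7 to 18.2, with single regions from 5.12-fold to 77.6-fold), followed. Larger ratios among abundant loci were found on chromosome 17 from 57338860 to 57361700, with 2464 RPM in pEGC and 28.8 RPM in pFF (85.5-fold, 77.4 to 94.7), and on chromosome 13 from 135942423 to 135961041, with 1983 RPM and 28.8 RPM (68.8-fold, 62.3 to 76.2). The locus on chromosome 1 from 132366977 to 132488591 held 13 regions and was 66.6-fold higher in pEGC (61.2 to 72.6, with its 2 larger parts at 73.2-fold and 26.9-fold), and that on chromosome 8 from 99419361 to 99469039 held 10 regions and was 57.0-fold higher (51.1 to 63.8). Single regions of the chromosome 8 locus ranged from 15.6-fold to 136-fold. The locus with the most regions, 35 over 165 kb, lay on chromosome 7 from 52893854 to 53058544, with 568 RPM in pEGC and 7.46 RPM in pFF (76.1-fold, 62.6 to 93.5). Its single regions ranged from 19.8-fold to 336-fold. On the X chromosome, 8 regions from 58368407 to 58400170 were 9.16-fold higher in pEGC (8.75 to 9.59).

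**Figure D4:**
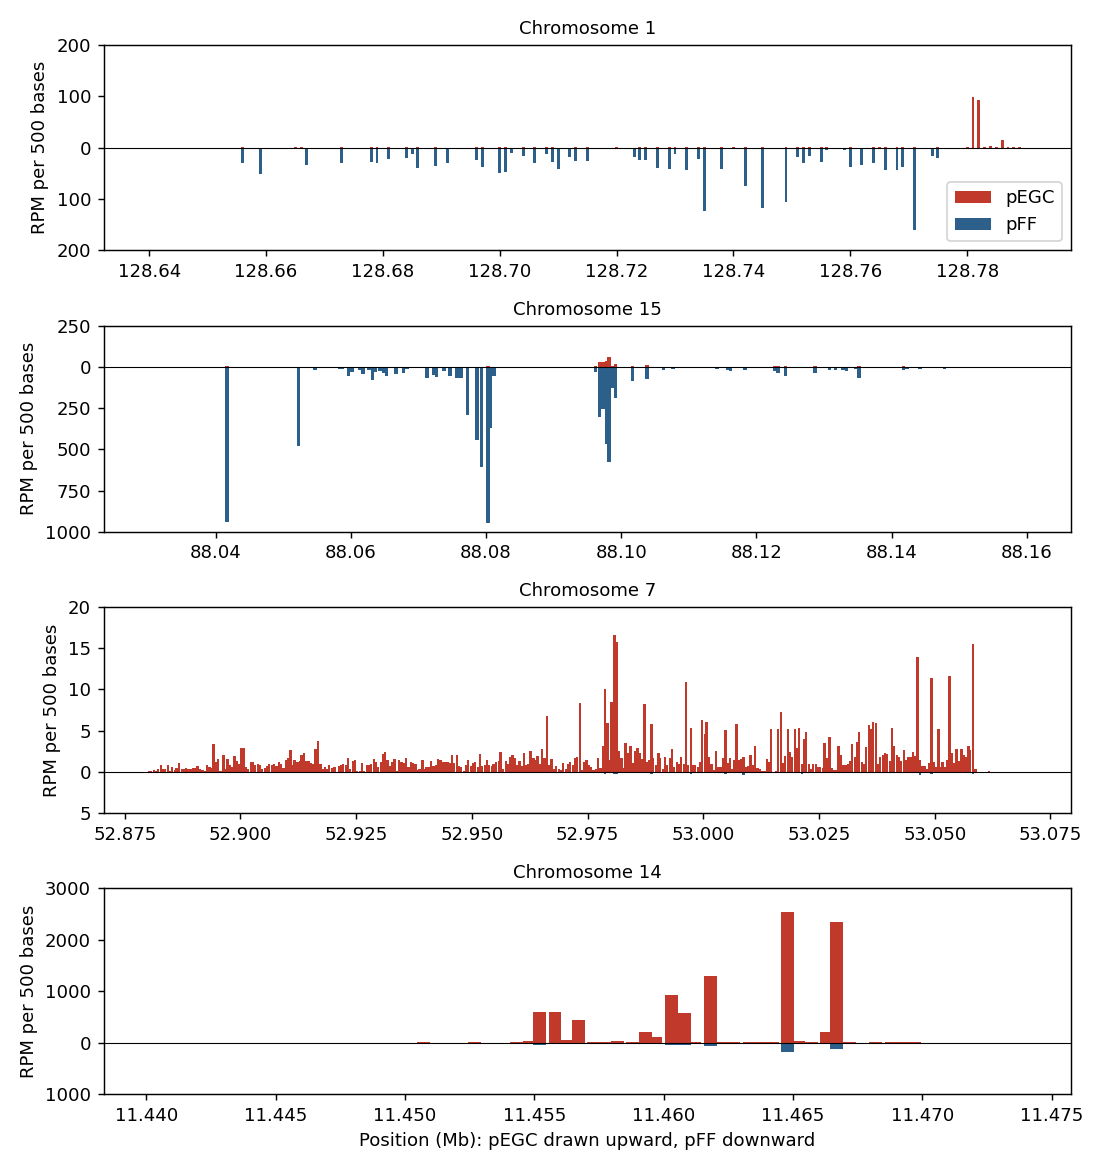
RPM per 500 bases along 4 loci, with pEGC drawn upward and pFF downward and the position in Mb on the horizontal axis. The loci on chromosomes 1 and 15 show separate peaks in pFF, that on chromosome 7 shows reads across its whole span in pEGC, and that on chromosome 14 shows peaks in pEGC far above pFF (16.7-fold over the locus).

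The single regions listed for the largest ratios had almost no reads in the other library, so their folds are loosely bounded. Because 0 reads counted as the floor of 3, a region with 0 reads ranked below an otherwise equal one with 1 read. Regions absent from the other library could therefore miss the list, and every listed region had at least 1 read there. The order given below is that of this rule. In pFF the leading region lay on chromosome 5 from 54976337 to 54977392, with 1768 reads in pFF and 1 in pEGC, a 1669-fold difference (299 to 65976). A second region of that neighbourhood, from 54974469 to 54974899, had 2464 reads in pFF and 3 in pEGC (776-fold, 265 to 3763). Next came chromosome 4 from 97087005 to 97087112, with 1926 and 2 reads (909-fold, 251 to 7514), and chromosome 8 from 40827445 to 40830792, with 873 and 1 reads (824-fold, 148 to 32596). The other 6 of the leading 10 lay on chromosomes 1 (2 regions), 2, 6, 8 and 15, with 654 to 1791 reads in pFF and 1 to 3 in pEGC. In pEGC the leading region lay on chromosome 3 from 86468837 to 86470911, with 590 reads in pEGC and 1 in pFF (625-fold, 112 to 24721), followed by chromosome 7 from 52576559 to 52586090, with 543 and 1 reads (575-fold, 103 to 22755). Another pair lay on chromosome 1, from 267974664 to 267975046 with 428 reads in pEGC and from 267973135 to 267973277 with 291, each with 1 read in pFF. The remaining 6, on chromosomes 7, 8, 11, 12, 13 and 14, had 297 to 326 reads in pEGC and 1 in pFF. With each position counted once, all 20 ratios kept their direction and shrank. Part of this is built in, since the lower library, with 1 to 3 reads, has few positions to lose. Short regions also run out of new positions, such as the 108 bases on chromosome 4 with 1926 reads in pFF. The log2 ratio of pEGC over pFF at the chromosome 3 region went from 9.29 to 6.82, within its counting interval, and 8 of the 20 left theirs. These were the regions on chromosome 4 (from -9.83 to -4.79), chromosome 5 (from -9.60 to -5.04 at 54974469 and from -10.71 to -6.87 at 54976337), chromosome 2 at 52212602 (from -9.15 to -6.50) and chromosome 6 at 20820978 (from -9.14 to -7.30) among those higher in pFF. Among those higher in pEGC they were the pair on chromosome 1 (from 8.82 to 6.29 and from 8.27 to 5.44) and the region on chromosome 8 at 58963588 (from 8.40 to 5.51).

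Apart from the chromosome 6 block, the regions with the most reads were found in both libraries. The region on chromosome 2 from 5165729 to 5173464, a continuous stretch of 7736 bases, had 26417 RPM in pEGC and 11713 RPM in pFF, 2.26-fold higher in pEGC (2.24 to 2.27). A shorter region on chromosome 2 from 104169880 to 104171558 had 4896 RPM in pEGC and 2714 RPM in pFF (1.80-fold, 1.78 to 1.83). Both directions turned when each read position was counted once, to log2 ratios of -0.33 and -0.38, a measure that saturates in regions as deep as these. The region on chromosome 14 from 11463479 to 11469939, part of the most abundant pEGC locus, was 16.8-fold higher in pEGC (16.3 to 17.3). The region on chromosome 9 from 69437811 to 69456812 was 35.0-fold higher in pFF (33.8 to 36.2). With each position counted once their log2 ratios of pEGC over pFF shrank from 4.07 to 1.60 and from -5.13 to -2.79, and that of the region on chromosome 1 at 138127337 from -2.20 to -0.53.

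Chromosomes were compared over 1880 windows of 1 Mb without the block, whose median log2 ratio of pEGC over pFF was 0.21. Chromosome 8 had the highest median, 0.43 over 100 windows, which was above 99.4% of 10000 random sets of as many windows. Chromosome 16 had the lowest, -0.03 over 55 windows, above 3.13% of random sets. The X chromosome, with a median of 0.26, was above 71.7% of random sets. With 19 chromosomes examined, single values this far out are not rare by chance. Of the differing regions, the share higher in pEGC ranged from 60.6% on chromosome 10 to 82.8% on chromosome 7. The X chromosome held 3.42% of the pEGC reads outside the block and 2.77% of the pFF reads.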

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

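The tests of the chromosome 6 block, and the alternatives that leave the block out, were chosen after the result was seen, as was the limit on calls kept below; the other bounds in this part were set before their values were computed. Reads that belonged to no region, because fewer than 20 pooled reads lay together, entered no comparison of regions. These reads made up 9.87% of the pEGC reads and 4.55% of the pFF reads. They were denser close to abundant regions. Within 10 kb of a region with at least 200 pooled reads there were 2414 such reads per Mb in pEGC and 1129 in pFF, and more than 100 kb away there were 274 and 138. Set against the reads in abundant regions without the block, the pEGC library had 37.3 nearby reads per 1000 and the pFF library 20.0.

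The chromosome 6 block took 30.6% of the pFF reads and 11.5% of the pEGC reads. Amplification of only a few positions as the cause is argued against by the spread of the reads, since the most frequent position held 2.18% of the block's pFF reads. Amplification of many positions was not tested. Ribosomal RNA left after poly(A) selection is a candidate explanation: bins of 50 bases with at least 1000 reads, joined over up to 500 bases, formed a span of 4.66 kb (broken between 249631 and 249851) and another of 1.70 kb, near the textbook lengths of 28S (about 4.8 kb) and 18S (about 1.9 kb) RNA, with a short one between them. The sequence that would decide was not used here, and the spans did not differ by 1 factor, being 1.95-fold and 3.09-fold higher in pFF. A difference between the cultures or their RNA preparation stays open, because each culture had 1 library.

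More regions were 4-fold higher in pEGC than in pFF, 2.87 for each region higher in pFF. The block's share of the reads accounts for part of this and not the whole, since the quotient stayed at 1.92 without it. Repeated positions as a cause stay open. The quotient was 1.94 with each position counted once as well, above the bound of 1.5 set to exclude them. That bound did not allow for calls lost through the way of counting itself. With the block left out, only 52.0% of the regions higher in pEGC and 51.0% of those higher in pFF kept their call. Deep regions running out of new positions, or distinct counts falling under the minimum of reads, could each lose calls, and neither was tested. The test was therefore taken as void, by a limit on calls kept that was set after these values were seen. Genomic DNA spread over the pEGC library is argued against: the excess of pEGC reads outside regions was 9.50 times as dense near abundant regions as far from them, and the far excess of 135 reads per Mb would put 0.230 reads into a region of 1703 bases, the median width of those higher in pEGC. Leaving the 50 regions with most reads out of the total lowered the quotient to 1.68. The share of reads taken by abundant regions outside the block was not tested apart from the block. Centring the ratios lowered the quotient to 1.22 (trimmed mean of M-values), but such a scaling sets the balance by its construction and so decides nothing. A wider set of transcripts or more unspliced RNA in pEGC may account for what remains; both are hypotheses, not tested with an annotation, and cell type and library preparation are confounded with 1 library each.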

How the results depend on the processing

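Each culture had 1 library, so no replicate could be left out and no test of the conditions was run. No paired analysis was possible because the groups have 1 library each. Depth limits the comparison in regions under 50 reads, and the size of the fold wherever 1 library holds only a few reads. Gene lists could not be evaluated under any setting. The number of regions higher in pEGC exceeded that higher in pFF under every scaling, threshold and region definition tried. The 6606 and 2303 regions became 4194 and 3438 with the trimmed mean of M-values, so 55.0% of the differing regions were higher in pEGC. With the median of ratios they became 4144 and 3501 (54.2%). Counting each position once gave 2731 and 1411 (65.9%), with or without the block. The share was 62.7% with the total without the 50 regions with most reads and 65.8% without the block. Minimums of 20, 200 and no reads gave 14411 and 3876 (78.8%), 1973 and 888 (69.0%), and 14865 and 3941 (79.0%). The 8-fold rule gave 3774 higher in pEGC (70.0%). Dropping the interval changed nothing, since every region with 50 reads that was 4-fold different also met it. Join distances of 1000 and 5000 bases gave 3764 and 1442 (72.3%) and 2006 and 875 (69.6%), by construction with fewer regions, and windows of 10 kb gave 79.5%. With the 1000-base distance 30844 regions were detected in pEGC, 24032 in pFF and 20929 in both, and with 5000 bases 12591, 11565 and 10039. A limit of 1 read with no RPM limit gave 74545 in pEGC, 73214 in pFF and 72224 in both, which says little because every region holds at least 20 pooled reads. The scalings changed the detected numbers to 61172 and 53994 (trimmed mean of M-values) and 59435 and 53994 (median of ratios). A limit of 50 reads with no RPM limit gave 28248 in pEGC, 20868 in pFF and 16910 in both. Pearson r of 0.698 moved to 0.640 with distinct positions (0.639 without the block), 0.675 without the 50 regions in the total, 0.683 without the block, 0.558 and 0.762 with pseudocounts of 0.1 and 5, 0.669, 0.778 and 0.809 with join distances of 100, 1000 and 5000 bases, and 0.722 with 10 kb windows. Spearman rho of 0.506 moved to 0.512 with distinct positions (0.512 without the block), 0.455, 0.638 and 0.759 with those join distances, and 0.639 with the windows. Counting each position once left 0.151% of the pEGC and 0.268% of the pFF reads in the chromosome 6 block and 18.7% and 13.1% outside regions, since deep regions run out of new positions. That setting turned the log2 ratio of the chromosome 2 region at 5165729 to -0.33 (-0.33 without the block) and of that at 104169880 to -0.38 (-0.38), for which saturation is a limit of the measure and the cause was not tested. Of the 27 listed regions, 20 stayed within their counting interval with the trimmed mean of M-values and with the median of ratios, and 12 with distinct positions. The 20 that stayed under these scalings were those with the largest ratios, whose intervals are wider than the shift. The 7 listed for their number of reads all moved, so the count reflects the width of the intervals. The filter to regions with 20 pooled reads was already part of the main setting, and thinning pFF to the pEGC total of reads in regions changed no result beyond its bounds, though with the block in that total it did not equalise the depth outside the block.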

Other observations

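Regions higher in pEGC were wider than those higher in pFF. Among regions with 200 to 500 reads in the higher library, the median width was 2384 bases over 1099 regions higher in pEGC and 892 bases over 446 regions higher in pFF. With the trimmed mean of M-values, a scaling added here after the data had been seen, the medians were 2264 bases over 704 regions and 905 bases over 666. Of 298 regions at least 10 kb wide, 94 were 4-fold higher in pEGC (31.5%) and 15 in pFF (5.03%), against 20.4% and 7.17% of the 31908 narrower regions with enough reads to qualify. With the trimmed mean of M-values these shares were 22.5% and 7.38% of the wide and 12.9% and 10.7% of the narrower regions. The loci were compared in another measure. Loci of 10 or more regions were thinned to 2000 reads of their higher library, and those with fewer reads were left out. A median of 85.2% of the 500-base windows held a read in 87 of 101 loci higher in pEGC (quartiles 76.1 and 94.1) and 67.4% in 23 of 30 loci higher in pFF (quartiles 53.4 and 78.5). Reads of pFF repeat positions more often (50.1% distinct against 57.5% in regions of like depth), which lowers their spread at equal read numbers. Matched on distinct positions instead, also added after the data had been seen, the differences were smaller and kept their direction. With 100 to 250 distinct positions the median widths were 2577 bases over 1331 regions and 1326 bases over 436. With 1000 positions drawn from each locus that had as many, 84.6% of the windows were occupied in 95 loci higher in pEGC (quartiles 76.8 and 92.7) and 70.8% in 23 higher in pFF (quartiles 61.6 and 80.4). These loci were picked because they differ, and the regions' limits come from both libraries, so the values are no measure of the libraries as a whole. The occupancy of each locus was measured in its higher library only. A trait of the loci therefore cannot be told apart from a trait of the library. Close to the continuous region of chromosome 2 with the most reads outside the block lay a second unbroken stretch, from 5192874 to 5213288, with 2589 RPM in pEGC and 761 RPM in pFF (3.40-fold, 3.33 to 3.48), which was chosen after its values were seen.

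A hypothesis fixed before its test was that loci higher in the same library lie next to each other beyond the length of a transcript. Among 1118 pairs of neighbouring loci 250 kb to 1 Mb apart, 60.8% had the same direction. The median of 10000 shuffles of the directions was 59.3%, and the share lay above 84.7% of them and under the bound of 62.2% set in advance, so such domains were not detected.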
